A study of Vitis vinifera with 60 samples.

How the data were processed

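Berries of 5 red-berried cultivars were collected at 4 stages, with 3 biological replicates each, per the labels. Total RNA came from about 400 mg of ground pericarp, and non-directional TruSeq libraries were made from 2.5 µg of it and sequenced on a HiSeq 1000, per the labels' protocols and the series design. The submitters' processing notes name TopHat2 2.0.6 and Cufflinks 2.0.2 without giving their roles. The genome build and the annotation are not given in the sources used here. Because the libraries carried no strand, reads of a gene and of an antisense partner cannot be told apart.

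The deposited table holds FPKM values, fragments scaled to transcript length and to the number of fragments. Its name calls them means, and its column headers give a cultivar and a stage without a replicate number. They were therefore taken as the authors' means per cultivar and stage. The table has 29287 rows and 20 columns. Of the rows, 608 join 2 or more locus tags, and 2828 are at 0 in every column. The column totals ran from 787405 to 1096120 FPKM. FPKM holds no read count, so the low values were searched for a common step of a single read. Over all 190 pairs of columns, a median of 3.36% and at most 6.27% of the genes under 0.05 FPKM in both shared a ratio, against 1.61% and at most 1.94% for smooth curves. There was thus an excess at single ratios, but it held few genes, so no depth was derived from it and no counting interval was computed. The values are means, so the spread of the replicate libraries is unknown too, and columns carry no replicate number.

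None of the locus tags matched the reference table of gene names (0 matches), and the deposited table does not pair tags with names. Gene groups that had been fixed by functional name before the data were examined were therefore not tested. The rule fixed for named genes took, for each step, genes past the threshold that moved the same way in all 5 cultivars and had a mean of at least 10 FPKM in the higher stage, by size of change, and required a functional name. Its name condition could not be applied, so it was dropped after the data were seen. The 2 largest rises and 2 largest falls of each step are given, which is fewer than the rule set. For cultivars the rule took genes above and below the others in each cultivar. Here only the 2 furthest above and the 2 furthest below over all 5 contrasts together are given. Barbera, Negroamaro and Primitivo are thus without a named gene. The most abundant genes of each stage were the other part of the rule. Counts of genes detected, runs of neighbours, exact zeros and the comparison of harvest columns were chosen after the data were seen.

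Tests were run on log2(FPKM + 1) for the 18207 genes with a mean of at least 1 FPKM over the 20 columns, with R 4.3.3 and limma 3.58.1. The model held stage and cultivar, with 12 residual degrees of freedom, a mean-variance trend and Benjamini-Hochberg adjusted p under 0.05, two-sided. The residual is the variation of stage changes between cultivars. A moderated F test over cultivars, and a contrast of each cultivar with the mean of the other 4 at a log2 difference of at least 1, used the same fit, with the 4 stages as repeats, so they speak of these vines and this season. No paired fit of replicates could be made. Column measures were compared with an exact permutation test of stage labels within cultivars. Runs were 5 or more tested genes adjacent by tag number on a scaffold field, all changed at least 2-fold in one direction and past the threshold, and were compared with 2000 shuffles of the genes. Python with numpy, pandas, scipy and matplotlib was used for these.

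The fit was tested on simulated data for soft against touching berries, with 18207 genes, the real residual spreads and 200 genes moved. It recovered 30% of genes moved by 0.5 log2 units, 70% at 1, 98% at 2 and 100% at 4, and 8 of the 157 genes called had not been moved. In the real data 55.4% of genes were called at this step. The adjusted threshold depends on that share, so these recovery rates need not hold for the real comparison. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, upper-quartile scaling, quantile normalization, robust hyperparameters, each cultivar left out, and no cultivar term. Scaling to equal total FPKM or to the total outside the 10 highest genes, and exchanging or leaving out the harvest columns labelled Negroamaro and Primitivo, were added after the data were seen, as were counts of 2-fold changes under each scaling.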

Results

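Transcripts of the berry pericarp, the berry without its seeds, were measured by RNA sequencing in 5 red-berried grapevine cultivars grown in one vineyard in the 2011 season. The cultivars were Sangiovese, Barbera, Negroamaro, Refosco and Primitivo. Berries were sampled at 4 stages, namely when they were pea-sized, when they were beginning to touch within the bunch, when they had turned soft, and when they were ripe for harvest. The labels list 3 biological replicates for each of the 20 combinations of cultivar and stage, 60 libraries in all. The deposited table gives one FPKM value per gene for each combination, which is the authors' mean, so neither the spread between replicate berries nor the read depth behind a value is known. The cultivar was therefore the unit of replication for stages, each SD below is the spread across the 5 cultivars, and p-values compare a change with its variation between cultivars. Genes are given by the locus tags of the table, because none of them matched the reference table of gene names. The 2-digit field after VIT_ in a tag is called its chromosome field here, with 00 for sequence not placed on a chromosome. The genome build is not given in the sources used here.

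In the deposited values fewer genes were detected in soft and harvested berries than in younger ones, and the most abundant genes took their largest share in soft berries. Pea-sized berries had 17954 ± 105 genes (SD, n = 5 cultivars) at 1 FPKM or more, touching berries 17343 ± 118, soft berries 16346 ± 294 and harvested berries 16161 ± 185. From pea-sized to harvested berries the number fell by 1793 ± 281, and it was lower in 5 of 5 cultivars, while from soft to harvested berries it was lower in 4 of 5. At 0.1 FPKM or more the number was higher at harvest than in soft berries in 3 of 5 cultivars, by 26.2 ± 117 on average, and in 5 of 5 fewer genes were at 0. Over the same stages the 10 most abundant genes of each column took 6.16% ± 0.792, 13.2% ± 2.90, 25.6% ± 3.12 and 19.6% ± 2.29 of the total FPKM, and the share was higher in soft than in touching berries, and lower at harvest than in soft berries, in 5 of 5 cultivars. Both measures differed between stages in a two-sided exact permutation test that exchanged stage labels within cultivars (p = 9.04e-06 for the number of genes and p = 3.01e-06 for the share, the latter being the smallest the 331776 assignments can give; Benjamini-Hochberg adjusted over 9 measures, 2.71e-05 and 1.36e-05). In this exact permutation test a single pair of stages cannot go below p = 0.0625 with 5 cultivars. The share in touching berries was lowest in Refosco, at 8.36%, and the gene that led the other touching columns was listed at 0 there. Values listed at 0 were kept in all tests. Counts at a fixed FPKM depend on the scaling of the columns and on depth, which is unknown. The median of the genes tested fell from 14.4 ± 0.0755 FPKM in pea-sized to 9.76 ± 0.492 FPKM in harvested berries. The counts were not repeated under another scaling, so a general shift of the values remains possible as a source of the decline.

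The genes at the top of the abundance list changed with ripening. Pea-sized and touching berries shared 8 of their 10 most abundant genes, and soft and harvested berries also shared 8, whereas touching and soft berries shared 3. The gene with the highest mean in both touching and soft berries was VIT_19s0014g02740, on chromosome field 19. It took 0.334% to 1.91% of the total FPKM in pea-sized berries, 6.53% to 16.9% in soft berries and 1.06% to 4.25% in harvested berries. In touching berries it took 7.17% to 9.44% in 4 cultivars and was listed at 0 in Refosco, where it had taken 1.91% in pea-sized berries and took 16.9% in soft ones. The entry that joins VIT_18s0001g14260 and VIT_18s0001g14270 had the highest mean in pea-sized berries, 7403 ± 4812 FPKM. The entry that joins VIT_08s0056g01600 and VIT_08s0056g01610 had the highest mean at harvest, 36270 ± 26360 FPKM, and the column labelled Negroamaro harvest was the highest of the 5 at 9.14% of its total. By the median of the 5 harvest columns VIT_19s0014g02740 was higher, at 33140 FPKM against 27290 FPKM for this entry. Where an entry joins several tags, or a gene has near-identical copies, the authors' estimate may divide reads between them, so such values are uncertain.

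Stage was the main difference between the columns. The leading axis of a principal component analysis held 58.2% of the variance and placed the 10 columns of pea-sized and touching berries between -107.5 and -57.96 and the 10 columns of soft and harvested berries between 48.78 and 130.9. On a scale from 0, the mean of the other 4 cultivars' pea-sized berries, to 1, the mean of their harvested berries, touching berries lay at 0.170 ± 0.0480 and soft berries at 0.714 ± 0.0551 (SD, n = 5). Soft berries of Sangiovese were least advanced on this scale at 0.645 and those of Negroamaro most advanced at 0.776. Refosco had the lowest value of touching berries, 0.101, and Barbera the highest, 0.236.

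**Figure D1:**
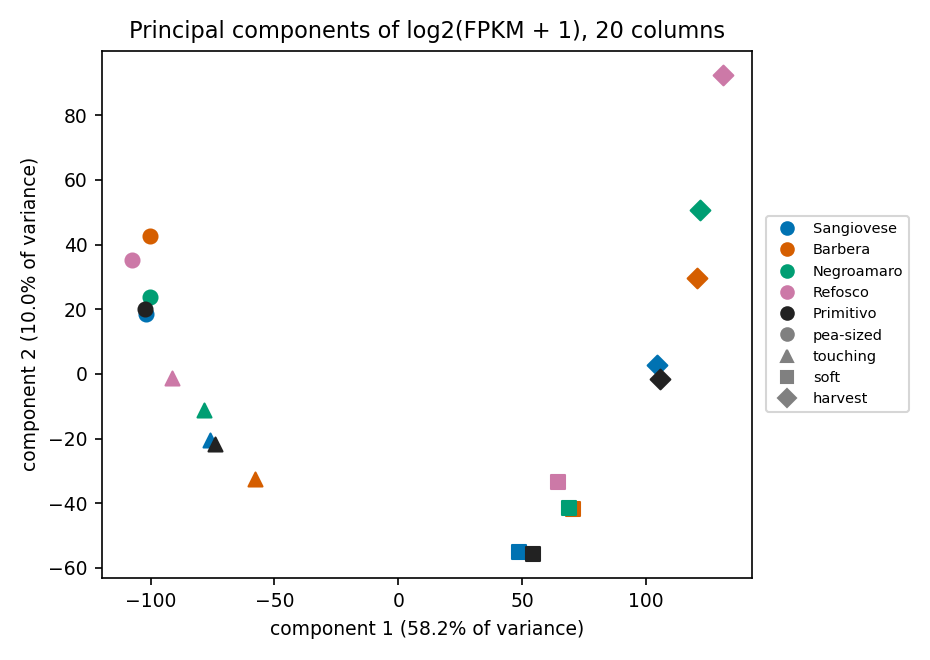
Principal components 1 and 2 of log2(FPKM + 1) over the genes tested, with one point for each of the 20 columns, coloured by cultivar and shaped by stage. Pea-sized and touching berries lie between -107.5 and -57.96 on component 1, which holds 58.2% of the variance, and soft and harvested berries between 48.78 and 130.9.

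Growth from pea-sized to touching berries changed the fewest genes of the 3 steps, and its larger changes were mostly falls. VIT_01s0011g05110, on chromosome field 1, rose from between 0.230 and 46.0 FPKM in the 5 cultivars to 676 ± 641 FPKM, a log2 change of 6.61 (SE 1.38, limma adjusted p = 0.00347, higher in 5 of 5 cultivars). The same gene was among the 10 most abundant of soft berries, at 8823 ± 5389 FPKM. VIT_00s0323g00060 rose from between 0.807 and 31.3 FPKM to 229.8 ± 174.8 FPKM, a log2 change of 4.52 (SE 0.59, adjusted p = 9.48e-05). VIT_19s0027g01810 fell from 117.4 ± 111.5 FPKM to between 0 and 0.621 FPKM, a log2 change of -6.05 (SE 0.43, adjusted p = 4.1e-07). VIT_13s0019g01520 fell from 108.9 ± 106.4 FPKM to between 0 and 0.321 FPKM, a log2 change of -5.88 (SE 0.51, adjusted p = 2.8e-06). Log2 changes and differences, and the 2-fold and 8-fold counts, are on the log2(FPKM + 1) scale, which understates the change of low genes. Folds of the summed level of a run, given below, are plain ratios of FPKM.

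At this step 4165 of the 18207 genes tested changed, 2253 upward and 1912 downward. Of these, 386 rose and 926 fell at least 2-fold, and 371 and 902 of them moved in that direction in all 5 cultivars. From pea-sized to touching berries 4 genes went from at least 10 FPKM in all 5 cultivars to under 1 FPKM in all 5, and 0 went the other way. One run of 6 neighbouring genes on chromosome field 10 fell together, from a summed 33.4 FPKM to 3.33 FPKM, where 2000 shuffles of the genes gave at most 5 genes in runs (permutation p = 0.0005, the smallest they can give). Without Barbera the count of changed genes was 2407. The share of changed genes that rose was 54.1%, and it was 25.9% when columns were scaled to equal total FPKM, a scaling chosen after the data were seen.

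Softening changed the most genes of the 3 steps, and in the deposited values more of them fell than rose. VIT_11s0016g04920, on chromosome field 11, rose from 3.77 ± 4.63 to 5650 ± 2312 FPKM, a log2 change of 10.70 (SE 0.61, limma adjusted p = 5.91e-09, higher in 5 of 5 cultivars). VIT_04s0079g00690, on chromosome field 4, rose from between 0 and 2.49 FPKM to 1428 ± 743 FPKM, a log2 change of 9.71 (SE 0.26, adjusted p = 4.61e-12). VIT_02s0154g00320 fell from 736 ± 532 to 3.87 ± 5.17 FPKM, a log2 change of -7.36 (SE 0.46, adjusted p = 1.53e-08). VIT_18s0122g00290 fell from 122.3 ± 52.0 to 0.110 ± 0.0703 FPKM, a log2 change of -6.65 (SE 0.27, adjusted p = 2.64e-10). Going by the switch between under 1 FPKM and at least 10 FPKM in all 5 cultivars, 10 genes turned on and 23 turned off at this step.

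In soft against touching berries 10089 genes changed, of which 2526 rose and 7563 fell. At least 2-fold changes were 951 rises and 3260 falls, and 8-fold changes were 182 rises and 293 falls. The median gene fell by 0.26 on the log2 scale in the deposited values, against -0.04 after upper-quartile scaling, 0.07 after quantile normalization and -0.45 at equal total FPKM. The share of changed genes that rose was accordingly 25.0% as deposited, 45.7% after upper-quartile scaling, 54.9% after quantile normalization and 13.7% at equal total FPKM. At least 2-fold changes were 1279 rises and 2468 falls after upper-quartile scaling, 1466 and 2081 after quantile normalization, and 758 and 4111 at equal total FPKM.

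**Figure D2:**
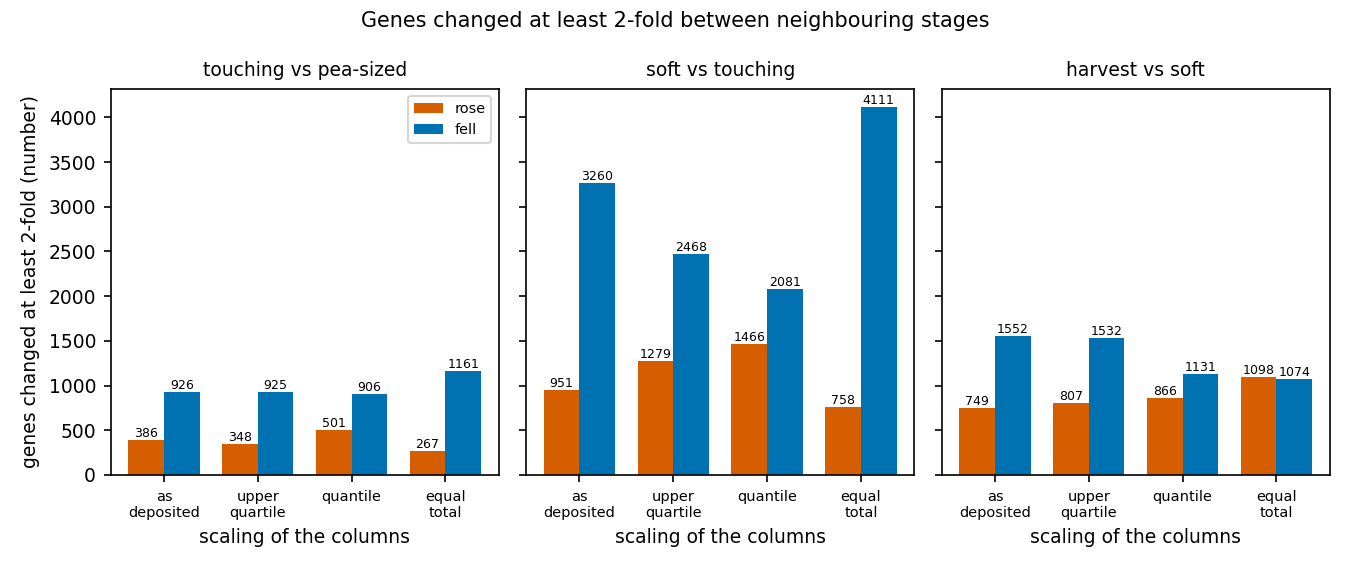
Number of genes that rose or fell at least 2-fold at each step between neighbouring stages, with adjusted p under 0.05, in bars, for 4 scalings of the columns taken singly. Under these scalings falls outnumbered rises at the steps to touching and to soft berries, by 2081 against 1466 at softening after quantile normalization, while at harvest equal total FPKM gave 1098 rises and 1074 falls.

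Neighbouring genes moved together at softening more often than shuffled genes did. Among genes falling at least 2-fold, 133 lay in 23 runs of 5 or more adjacent tested genes, where 2000 shuffles of the genes gave a median of 11 and at most 46 (permutation p = 0.0005, the smallest they can give). A run of 11 genes on chromosome field 16 fell from a summed 228 to 47.5 FPKM, and a run of 7 genes on chromosome field 1 fell from 1484 to 152.7 FPKM. Fewer genes that rose did so in runs, 23 in 4 runs, against at most 5 in the shuffles (permutation p = 0.0005). A run of 7 on chromosome field 6 rose from 37.2 to 261 FPKM and stood at 69.3 FPKM at harvest, and a run of 5 on chromosome field 5 rose from 338.5 to 1587 FPKM and stood at 7120 FPKM at harvest. These are means over cultivars. For the 6 neighbours on field 5 that include those 5 genes, the sum in Refosco fell from 645 to 524 FPKM at softening, while it rose in the other cultivars. Their soft mean was 956 FPKM without Negroamaro, which stood at 4115 FPKM.

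The step from soft to harvested berries raised groups of neighbouring genes. On chromosome field 16, scaffold field 100, 34 adjacent tested genes each rose at least 2-fold, with a median log2 change of 4.15 and a range from 2.82 to 5.27. Their summed level was 100.2 ± 120.1 FPKM in soft and 4713 ± 6259 FPKM in harvested berries, and it was higher at harvest in all 5 cultivars, by 11.9-fold in Sangiovese and by 305-fold in Refosco at the extremes as labelled. With the harvest columns labelled Negroamaro and Primitivo exchanged, the extremes would be 2.12-fold in Negroamaro and 358-fold in Primitivo, and without Refosco the harvest mean was 2071 ± 2388 FPKM. The harvest sums were 438 FPKM in Sangiovese, 1622 FPKM in Barbera, 15282 FPKM in Refosco, and 5569 and 656 FPKM in the columns labelled Negroamaro and Primitivo. A run of 9 genes on chromosome field 10 rose from 10.4 ± 6.79 to 1416 ± 1910 FPKM, with a harvest mean of 638 ± 910 FPKM without Refosco. By label it rose 97.3-fold in Negroamaro and 13.7-fold in Primitivo, and with their harvest columns exchanged 3.97-fold and 336-fold. Further runs rose on chromosome fields 5, 9 and 16, with 6, 8 and 6 genes. In total 63 genes that rose lay in such runs, against at most 5 in 2000 shuffles (permutation p = 0.0005, the smallest they can give). Of the genes that fell at least 2-fold, 11 lay in 2 runs, against at most 10 in the shuffles (permutation p = 0.0005). Neighbouring genes can be near-identical copies that share reads, and sequences were not used here, so the number of genes in a run is less certain than its summed level.

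**Figure D3:**
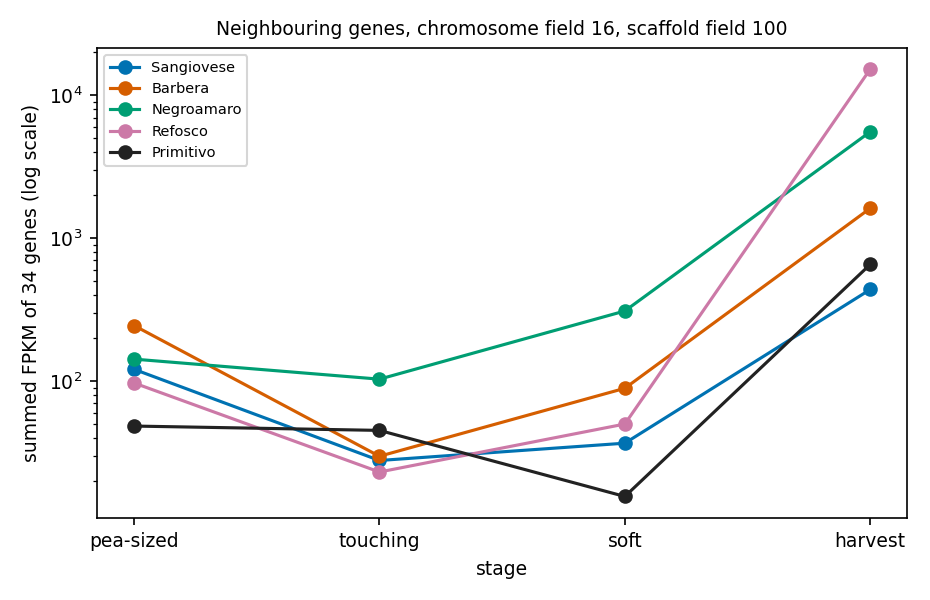
Summed FPKM, on a log scale, of the 34 neighbouring genes on chromosome field 16, scaffold field 100, by stage, with one line per cultivar as labelled. Every line is highest at harvest, from 438 FPKM in Sangiovese to 15282 FPKM in Refosco.

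The single genes with the largest rises at harvest belonged to the run on chromosome field 10. VIT_10s0042g00860 went from between 0 and 6.49 FPKM in soft berries to between 2.93 and 1612 FPKM, a log2 change of 5.35 (SE 1.15, limma adjusted p = 0.00221, higher in 5 of 5 cultivars). VIT_10s0042g00880 rose from 2.08 ± 1.34 to 318 ± 395 FPKM, a log2 change of 5.32 (SE 0.97, adjusted p = 0.000722). VIT_13s0019g00330 fell from 184.7 ± 68.4 to 3.97 ± 3.44 FPKM, a log2 change of -5.37 (SE 0.32, adjusted p = 3.23e-07). VIT_01s0011g05170 fell from 100.4 ± 64.2 to 3.24 ± 4.48 FPKM, a log2 change of -4.92 (SE 0.48, adjusted p = 8.81e-06). At this step 7186 genes changed, 2718 upward and 4468 downward, with 749 rises and 1552 falls of at least 2-fold. The rising share was 37.8% as deposited, 52.3% after quantile normalization and 65.8% at equal total FPKM, so which direction prevailed depended on the scaling. For changes of at least 2-fold, quantile normalization gave 866 rises and 1131 falls, and equal total FPKM gave 1098 rises and 1074 falls.

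Over the whole of ripening, soft and harvested berries against pea-sized and touching ones, 13601 genes changed, 4285 upward and 9316 downward. At least 2-fold changes were 1340 rises and 4468 falls as deposited, and 2427 rises and 2860 falls after quantile normalization. A set of 6 genes was under 1 FPKM in all 10 earlier columns and at 10 FPKM or more in all 10 later ones, and 19 genes did the reverse. The rising share was 31.5% as deposited, 45.8% after upper-quartile scaling, 55.9% after quantile normalization and 23.1% at equal total FPKM. Among the 13741 genes that changed at any of the 3 steps, 4776 had their highest mean log2 value in pea-sized berries. It was highest in touching berries for 4395, in soft for 1422 and in harvested for 3148. These counts are of the deposited values and were not repeated under another scaling.

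Some genes differed between cultivars on average over the stages. For these comparisons the 4 stages of a cultivar served as repeats, so the p-values do not rest on replicate plants. VIT_11s0052g01770, on chromosome field 11, averaged 8.06 FPKM over the 4 stages in Refosco, where it ranged from 0.281 to 30.2 FPKM, against 127 to 502 FPKM in the other 4 cultivars, a log2 difference of -5.94 (SE 0.60, limma adjusted p = 4.5e-05). VIT_05s0094g00350 averaged 0.332 FPKM in Sangiovese and 233 FPKM in the others, where it ranged from 0.0964 to 844.9 FPKM, a log2 difference of -4.85 (SE 0.93, adjusted p = 0.00535). Above the others in Refosco were VIT_00s0160g00280, at 138 against 17.1 FPKM (log2 difference 5.60, SE 0.96, adjusted p = 0.00335), and the entry that joins VIT_19s0014g05360 and VIT_19s0014g05370, at 115 against 8.88 FPKM (log2 difference 5.44, SE 0.91, adjusted p = 0.00295). A column of another cultivar reached 265.7 FPKM for VIT_00s0160g00280, which ranged from 14.1 to 332.9 FPKM in Refosco. For the joined entry a column of another cultivar reached 114 FPKM. The log2 differences compare means of log values, so they need not match the ratios of mean FPKM.

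A difference between cultivars in the level averaged over stages was called for 2973 genes, 16.3% of those tested; whether it was steady from stage to stage was not tested. At an adjusted p under 0.05 and a log2 difference of at least 1 from the mean of the others, 464 genes stood apart in Sangiovese, 375 in Refosco, 267 in Barbera, 122 in Negroamaro and 112 in Primitivo. With a pseudocount of 5 these counts were 167, 133, 86, 37 and 27, in the same order, and with one of 0.1 they were 589 in Refosco, 424 in Barbera, 190 in Negroamaro and 207 in Primitivo. At a mean of at least 5 FPKM they were 253, 227, 175, 68 and 58. Without Sangiovese 41 genes stood apart in Negroamaro and 35 in Primitivo, and without Refosco 63 and 38. The counts rose to 246 in Negroamaro without Primitivo, and to 250 in Primitivo without Negroamaro. The main counts of Negroamaro and Primitivo, and the 2973, also depended on the harvest columns labelled with those names. Left out, these columns gave 4522 genes differing between cultivars, 499 apart in Negroamaro and 458 apart in Primitivo, and 355 to 564 in the other 3. Without Sangiovese, 958 genes differed between cultivars, without Refosco 1634 and without Barbera 1961.

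The harvest columns labelled Negroamaro and Primitivo resembled each other's cultivar. Each column was described by its deviation from the mean of the 5 cultivars at its stage, gene by gene, and compared with the same deviations averaged over the earlier stages. The harvest columns of Sangiovese, Barbera and Refosco had their highest correlation with their own cultivar, with Pearson's r across genes from 0.373 to 0.503. The column labelled Negroamaro harvest had r = -0.0976 with Negroamaro and 0.452 with Primitivo, and the column labelled Primitivo harvest had r = -0.0873 with Primitivo and 0.442 with Negroamaro. Genes are not independent replicates, so no p is given for these values. Of 17 genes steadily at 5 FPKM or more or under 0.5 FPKM in each cultivar before harvest, and not alike in all 5, the column labelled Negroamaro matched Primitivo in 16 and Negroamaro in 8, and the column labelled Primitivo matched Negroamaro in 17 and Primitivo in 7. Values are given by label throughout, and none of the 4 counts of genes changed between stages moved by more than 1.5 times without these columns.

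**Figure D4:**
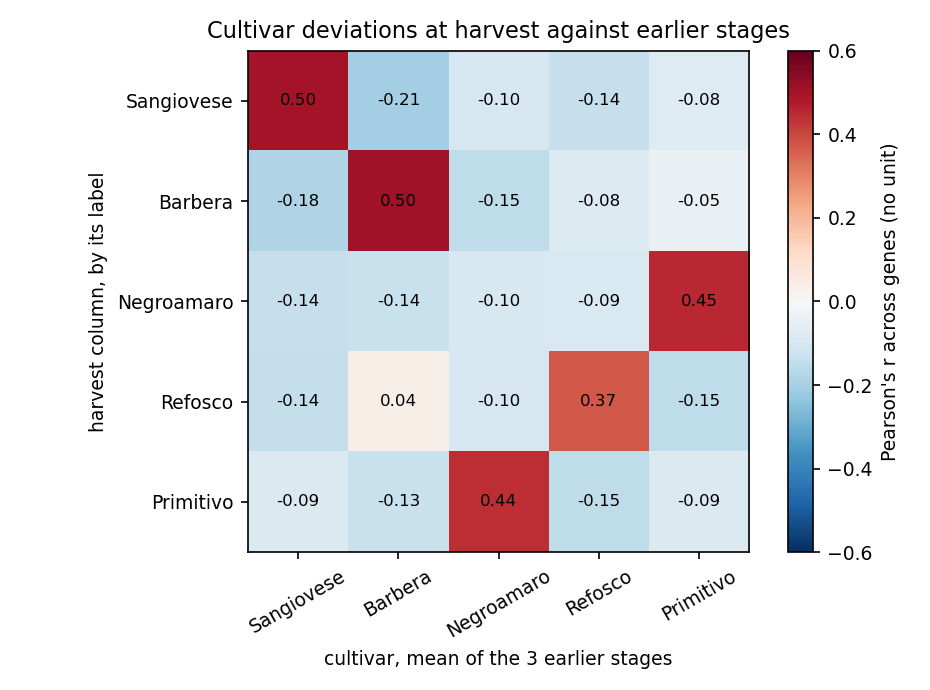
Pearson's r across genes between each harvest column, by its label in rows, and each cultivar's mean over the 3 earlier stages in columns, after the mean of the 5 cultivars was taken off at each stage. The column labelled Negroamaro has r = 0.452 with Primitivo, the column labelled Primitivo has r = 0.442 with Negroamaro, and the other 3 are highest with their own cultivar, at 0.373 to 0.503.

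The changes at softening were correlated between cultivars. Changes from touching to soft berries correlated across genes with r between 0.717 and 0.841 for all pairs of cultivars, and changes from pea-sized to touching berries with r between 0.558 and 0.764. Changes from soft to harvested berries had r between 0.0674, for Negroamaro with Primitivo, and 0.647 by label. With the harvest columns of these cultivars exchanged, r was between 0.525 and 0.763, and 0.572 for that pair. The number of genes that fell at least 2-fold at softening ranged from 3225 in Sangiovese to 4368 in Refosco, and the number that rose from 986 in Sangiovese to 1391 in Barbera. The change of one cultivar lay at least 2 log2 units from those of all the other 4 for 207 genes, against 558 at 1.5 log2 units and 83 with a pseudocount of 5. A cultivar lay above the others for 118 of these genes and below them for 99. Some genes thus had a cultivar apart on both sides, and these were counted for the upper one only. Counted so, of the 207, Barbera was the cultivar apart for 65, Negroamaro for 42, Refosco for 40, and Sangiovese and Primitivo for 30 each. With one value per cultivar and stage this difference could not be tested. Cultivars also differed more from each other late than early, with a median absolute log2 difference per gene, averaged over the 10 pairs, of 0.23 in pea-sized, 0.24 in touching, 0.31 in soft and 0.34 in harvested berries. With single cultivars left out these values ran from 0.21 to 0.24, 0.23 to 0.25, 0.30 to 0.32 and 0.32 to 0.36, and the increase was not tested.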

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

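The search for outlying columns, the test of low values above 0, and the upper-quartile and quantile scalings were fixed before the results were seen; the other tests in this part, and the bounds set on those scalings, were chosen after. Among 68 groups of 5 columns, 8 held a column far from the other 4, where chance gives about 1 in 20 for independent, normally distributed groups. Here the groups share columns, and many hold raw FPKM of genes picked for large changes, so that rate need not apply. VIT_19s0014g02740 was listed at 0 in Refosco touching berries against 62990 to 86665 FPKM in the others, and was highest in Refosco among pea-sized berries at 15412 FPKM against 2658 to 5938 FPKM. VIT_01s0011g05110 was at 46.0 FPKM in Negroamaro pea-sized berries against 0.230 to 4.68 FPKM, and VIT_02s0154g00320 at 13.0 FPKM in Primitivo soft berries against 0.667 to 2.49 FPKM. The most abundant gene took 9.14% of the column labelled Negroamaro harvest against 2.91% to 3.95% elsewhere. Negroamaro had 17551 genes at 1 FPKM or more in touching berries against 17264 to 17326. The total outside the 10 highest genes was 764870 FPKM in Sangiovese pea-sized berries against 745453 to 748384. Refosco pea-sized berries stood at -0.0172 on the ripening scale against 0.0209 to 0.0305.

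Abundant genes were sometimes listed at exactly 0. Where the median of the other 4 cultivars was 1000 FPKM or more, 19 of 1229 values were 0, or 1.55%, against 21 of 27293 values, 0.0769%, at a median of 100 to 1000 FPKM (Fisher's exact test, two-sided, p = 5.47e-16, over values that are not independent). Genes that were off in a cultivar at a stage would also leave low values above 0, but only 1 value lay above 0 and under 1% of that median, and in 15 of the 19 cases the cultivar reached 100 FPKM at another stage, which argues against a variant that hides the gene as the cause in those 15. A failed estimate in the authors' processing may be the source of these zeros. It stays open for the other cases, and no reads were used here that could decide it.

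The harvest columns labelled Negroamaro and Primitivo matched each other's earlier stages in on and off genes, while over whole profiles the latter was closest to Negroamaro soft berries (r = 0.962, the closest pair of columns, against 0.891 with Primitivo soft) and the former no closer to Primitivo soft (0.870) than to Negroamaro soft (0.874). Of the 36 genes steadily on in one and off in the other of these cultivars before harvest, 32 stood on the partner's side in both columns, or 88.9%. For a harvest response of the cultivars themselves, the lower correlation with the partner, 0.442, was set against the other 3 harvest columns. It was above their highest value with another cultivar, 0.0362. This correlation had itself raised the question before the bound was set, so it cannot decide on such a response. Less ripe berries would keep the state of those 36 genes in earlier stages. As the only cause they are argued against by 91.7% of these genes on the partner's side in the column labelled Negroamaro and 97.2% in that labelled Primitivo. The like comparison of the other 3 cultivars gave at most 9.09%. On the ripening scale the column labelled Primitivo was the lowest at harvest, at 0.894 against 0.906 to 1.05. Genes chosen as steady before harvest do not measure ripeness, so less ripe berries together with an exchange of both columns were not tested. An exchange of these columns, or of the 3 earlier stages instead, is a candidate explanation, and the table cannot say which.

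More genes fell than rose at softening in the deposited values, and the 10 highest genes alone are argued against as the cause. With columns scaled to the total outside their 10 highest genes, 24.8% of changed genes rose, as against 25.0% in the deposited values. That total averaged 776370 FPKM in touching and 778180 FPKM in soft berries, while the upper quartile fell from 36.4 to 30.4 FPKM. A larger share taken by abundant genes beyond the 10 highest was not tested and stays open. For changes of any size, the authors' normalization and a lower level of many transcripts cannot be told apart, since upper-quartile scaling gave 45.7% and quantile normalization 54.9%, the former assuming equal upper quartiles and the latter equal distributions. For changes of at least 2-fold, falls outnumbered rises under each of 5 scalings taken singly, but by only 1.42 times under quantile normalization, under the 1.5 times set as the bound, so the normalization stays open there too.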

How the results depend on the processing

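Leaving out or exchanging harvest columns, both total FPKM scalings, and all alternatives for runs and for genes detected were chosen after the data were seen; the rest were fixed before the data were examined. No paired analysis was possible because the columns are means that carry no replicate numbers. Gene groups by functional name and leaving out single replicates were not run, for want of names and of single libraries. The 16 named genes kept their direction and side of the threshold in all 264 of their alternatives. Of 186 alternatives for counts, 152 stayed within 1.5 times, or 1 SD for genes detected, and 34 did not. The causes were not tested. With a pseudocount of 0.1, genes apart were 424 in Barbera, 190 in Negroamaro, 589 in Refosco and 207 in Primitivo. With a pseudocount of 5 they were 167 in Sangiovese, 86 in Barbera, 37 in Negroamaro, 133 in Refosco and 27 in Primitivo, and 83 genes had a cultivar-specific softening change, against 558 at a gap of 1.5 log2 units. At a mean of at least 5 FPKM, which tests fewer genes, genes apart were 253, 175, 68, 227 and 58 in Sangiovese, Barbera, Negroamaro, Refosco and Primitivo. With the harvest columns labelled Negroamaro and Primitivo exchanged, 5224 genes differed between cultivars, 543 were apart in Negroamaro and 491 in Primitivo, and left out they gave 4522, 499 and 458. Leaving out each cultivar gave 2407 (Barbera) to 3595 genes from pea-sized to touching, 8747 to 9249 at softening, 5193 to 6720 at harvest, 12804 to 13296 over ripening, and 958 (Sangiovese) to 2563 between cultivars, with 1634 without Refosco and 1961 without Barbera. It gave 41 (Sangiovese) to 246 (Primitivo) genes apart in Negroamaro and 35 (Sangiovese) to 250 (Negroamaro) in Primitivo, with 63 and 38 without Refosco. The change in genes detected from pea-sized to harvest was -1443 at 0.1 FPKM and -2120 at 5 FPKM, and -1900 to -1714.5 with a cultivar left out at 1 FPKM. The longest run of genes rising at harvest held 34 genes in all alternatives except no filter, where low genes also enter and it held 24.

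Only 16 splits of the 10 columns of a step keep each cultivar on both sides, too few for a share under 0.05: the real split gave 4165 genes from pea-sized to touching (highest other 0), 10089 at softening (0) and 7186 at harvest (909). Of 100 splits that ignored cultivars, the highest others were 185, 3319 and 4152. Over ripening, only the real one of 100 splits within cultivars gave as many genes, 13601 against at most 551. In the other splits real stage changes enter the residual, so their counts are not those of data without stage effects. The share of 1 of 100 is the smallest that 100 splits can give. It speaks only to whether the stage labels matter at all. It cannot say how many genes would be called without stage effects. With cultivar names exchanged within stages, it was again 1 of 100 for 2973 genes between cultivars (highest other 114), 464 in Sangiovese (215), 267 in Barbera (5), 375 in Refosco (5) and 112 in Primitivo (85), and 2 of 100 for 122 in Negroamaro, where another assignment gave 248. In those assignments real cultivar differences enter the residual likewise, so the same limit holds for these counts. The splits were tests chosen after the counts were seen. Unknown depth leaves low values without an error.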

Other observations

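A few genes were steadily on in one cultivar alone, or off in one alone, over the 3 stages before harvest, taking at least 5 FPKM as on and under 0.5 FPKM as off. Primitivo had 4 genes on where the other 4 cultivars had them off, Sangiovese 2, Negroamaro 2 and Refosco 1, and Barbera had 0. Sangiovese had 4 genes off where the others had them on, and Negroamaro had 1. At harvest a single dividing value of 1.5 FPKM was used. All 4 of these Sangiovese genes were under it in Sangiovese. The single Refosco gene was at or above it in Refosco, and in Sangiovese so was 1 of the 2 genes on in that cultivar alone. None of the 4 Primitivo genes or the 2 Negroamaro genes reached 1.5 FPKM in the harvest column labelled with that cultivar.

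The Barbera column of pea-sized berries was the least like its own cultivar among the pea-sized columns. Its deviations correlated with those of later Barbera columns at r = 0.159 and with Refosco at 0.0989, across genes, while the other 4 pea-sized columns had r from 0.581 to 0.663 with their own cultivar. Of 35 genes steadily on or off in each cultivar in touching and soft berries, it matched Barbera in 21 and Refosco in 30. No explanation was tested.

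The gene clusters that rose at harvest differed widely between cultivars. The run of 9 genes on chromosome field 10 stood at 4529 FPKM in Refosco and 62.6 FPKM in Sangiovese at harvest, and the run of 6 on chromosome field 16, scaffold field 39, at 1432 and 75.9 FPKM. The run on chromosome field 5 had the other order, with 10089 FPKM in Sangiovese and 4946 FPKM in Refosco. These differences were not tested, since there is one value per cultivar and stage.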
